A study of Mus musculus with 11 samples.

How the data were processed

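The series holds 11 bulk RNA-seq libraries of mouse limb muscle stem cells, sorted by flow cytometry. Per the labels, tamoxifen-induced Cre at the Pax7 locus marked the cells with YFP, and the sort kept YFP+ cells negative for Sca-1, CD31 and CD45 (genes Ly6a, Pecam1 and Ptprc). Cells of geriatric mice (over 28 months) were divided by VCAM1 surface level into VCAM1-high (3 libraries), VCAM1-low (2) and VCAM1-negative (3), with gates set on the YFP+ cells of middle-aged mice. The middle-aged group (10 to 14 months by the sample labels, 12 to 14 months in the extraction protocol) has 3 libraries. Tamoxifen was given at 12 to 14 weeks of age in both age groups. The titles of the middle-aged libraries name YFP+ cells and no VCAM1 gate. Comparisons with them thus change age, gating and the time since labelling together. The gate names follow the sample titles. The series' design text calls the lower gates mid and low or negative, and it is not stated which name matches which. Per the labels' protocols, muscle was digested with collagenase and dispase, RNA was extracted with TRI Reagent, amplified with the SMART-Seq v4 low-input kit and sequenced as paired ends on an Illumina HiSeq.

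The submitters' processing notes name cutadapt 3.1, Bowtie2 2.1.0, STAR 2.7.5b, SAMtools 0.1.19 and genome build GRCm39, while the step each tool was used for is not given in the sources used here. The authors deposited RPKM values (mapped reads scaled by gene length and library size) for 20640 gene symbols in all 11 libraries. The tool that counted the reads, the annotation and the gene lengths behind the RPKM values are not given in the sources used here. Of these symbols 2161 are 0 in every library. Mitochondrially encoded genes were not analysed here.

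Depth was estimated from the deposited RPKM values, because reads of 1 gene step in multiples of a fixed amount. Multiplying low values (0.1 RPKM or less) of 3428 genes with a single transcript by transcript length gave the step that 1 read makes. The estimates run from 20.0 to 30.0 Mreads (M for mega). By library they are 25.5, 22.3 and 30.0 in the middle-aged replicates 1 to 3, 20.0, 24.3 and 27.7 in VCAM1-high, 21.6 and 24.1 in VCAM1-low, and 25.2, 21.7 and 23.0 in VCAM1-negative. Between 67.4% and 77.3% of the low values lay within 0.1 of a whole read, against 20% by chance. Lengths came from another annotation than the authors', so the depths are estimates. At the lowest depth 1 read of a 1 kb gene is 0.05 RPKM. RPKM summed over genes ran from 413666 to 455394 per library, 10395 to 11171 genes reached 1 RPKM, and the 10 most abundant genes held 6.80% to 12.3% of the sum.

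Values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3. Genes at 1 RPKM or more in at least 2 libraries were kept (11568 genes). One linear model with 4 group means was fitted to all 11 libraries, with a variance trend over mean level, and p-values were adjusted by Benjamini and Hochberg over the genes tested. A gene was counted as changed at adjusted p under 0.05 and an absolute log2 fold change of 1 or more. For members of a gene list, passing means adjusted p under 0.05 over all genes, and a second count adjusts over the list alone. The main comparisons are VCAM1-negative against VCAM1-high, VCAM1-high against middle-aged and VCAM1-negative against middle-aged. The 3 comparisons with VCAM1-low are secondary, since 2 libraries stand in that group. A limma F test asked which genes differ among the 4 groups. Errors beside fold changes are standard errors of the fit, and errors beside levels are standard deviations between libraries. Nothing in the labels says that replicates are separate animals, so the p-values measure only the spread between these samples.

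Before the data were examined, 37 gene lists (495 genes, 452 of them in the table) were fixed for stem cell markers, quiescence, myogenic steps, senescence, stress, metabolism, signalling and the other cell types of muscle. The 33 with at least 3 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the residuals of the fit. Sex-linked genes were left out. The lists are not independent of each other, as Col3a1 stands in both the matrix and the fibro-adipogenic progenitor list.

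Genes are named by a rule fixed with the lists. It takes Vcam1, Pax7, Cd63, Cd200, Ly6a, Pecam1 and Ptprc in each comparison. It adds the 8 largest rises and 8 largest falls of each main comparison (3 and 3 in a secondary one) among changed genes whose libraries do not overlap and whose higher group averages at least 5 RPKM. Predicted genes, clones, sex-linked genes and immunoglobulin or T-cell receptor genes are left out. It also takes up to 4 members of each list with the smallest adjusted p. The series title names CD63 and CD200, which the study may have chosen on these libraries, so their levels here are not independent evidence. Serpina3m, Serpina3n, C4b and Hbb-bs have close paralogs, so some reads may belong to a sister gene.

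Libraries carry replicate numbers 1 to 3. Same-numbered libraries were compared by the correlation of their deviations from the group means. For replicates 1, 2 and 3 this was 0.41, 0.58 and 0.40 between VCAM1-high and VCAM1-negative, 0.21, 0.33 and 0.55 between middle-aged and VCAM1-high, and -0.02, 0.03 and 0.08 between middle-aged and VCAM1-negative. For replicates 1 and 2 it was 0.49 and 0.51 between VCAM1-high and VCAM1-low, 0.52 and 0.57 between VCAM1-low and VCAM1-negative, and 0.15 and 0.03 between middle-aged and VCAM1-low. The deviations of the 2 VCAM1-low libraries mirror each other, so the 2 values of each such pair are not independent. The pairing thus comes from the data, as no label says what a number marks, and middle-aged and geriatric libraries cannot share an animal. A model with replicate number as a block was fitted to all 11 libraries and to the 8 geriatric ones. Because 0 genes passed between VCAM1-negative and VCAM1-high without a block, the naming rule was applied there to the geriatric block model, a choice made after the result was seen.

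Alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 RPKM, rescaling to an equal sum or by the median ratio, a model of only the 2 groups compared, the replicate block, an estimated correlation for lists, and leaving out each library in turn. Leaving out all number-3 libraries was added after they were seen to stand apart. Where a call is said to end without 1 library, other omissions may end it too. The model was tested on simulated data with 200 changed genes. At log2 shifts of 1, 2 and 3 it found 35.8%, 94.0% and 98.5% of those between VCAM1-negative and VCAM1-high (5 false calls, 11358 genes tested), and 44.8%, 100% and 100% with the geriatric block (1 false call, 11299 genes tested). Between VCAM1-high and middle-aged it found 43.3%, 92.5% and 100% (3 false calls, 11382 genes tested), and between VCAM1-negative and middle-aged 35.8%, 91.0% and 100% (4 false calls, 11367 genes tested). A shift of 1 on the extracellular matrix list was called in all 3 comparisons, with 0, 0 and 2 of the 32 other lists called. The 200 changed genes were placed only among well-expressed ones. Simulated libraries varied independently, except for a shift per replicate number in the geriatric block run. Real libraries of the same number deviate together, so the shares found are not the power in these data. Simulated genes were independent too, so camera's preset correlation was not tested where genes vary together.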

Results

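The first principal component (42.6% of variance) sets middle-aged libraries apart from geriatric ones. It places the middle-aged libraries at a mean of -41.3 (SD 8.73), VCAM1-high at -0.975 (SD 20.1), VCAM1-low at 21.7 (SD 22.3) and VCAM1-negative at 27.8 (SD 18.1). Among geriatric libraries this component goes with replicate number as well as gate. In VCAM1-high, VCAM1-low and VCAM1-negative it reads -9.24, 5.90 and 16.2 for number 1 and 21.9, 37.4 and 48.7 for number 2, and -15.6 and 18.5 for number 3 of VCAM1-high and VCAM1-negative. The second component (20.8%) sets the number-3 libraries of 3 groups apart from the rest. Correlations between libraries run from 0.941 to 0.975 within groups and from 0.875 to 0.988 between groups, the highest between the number-2 libraries of VCAM1-high and VCAM1-low.

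**Figure D1:**
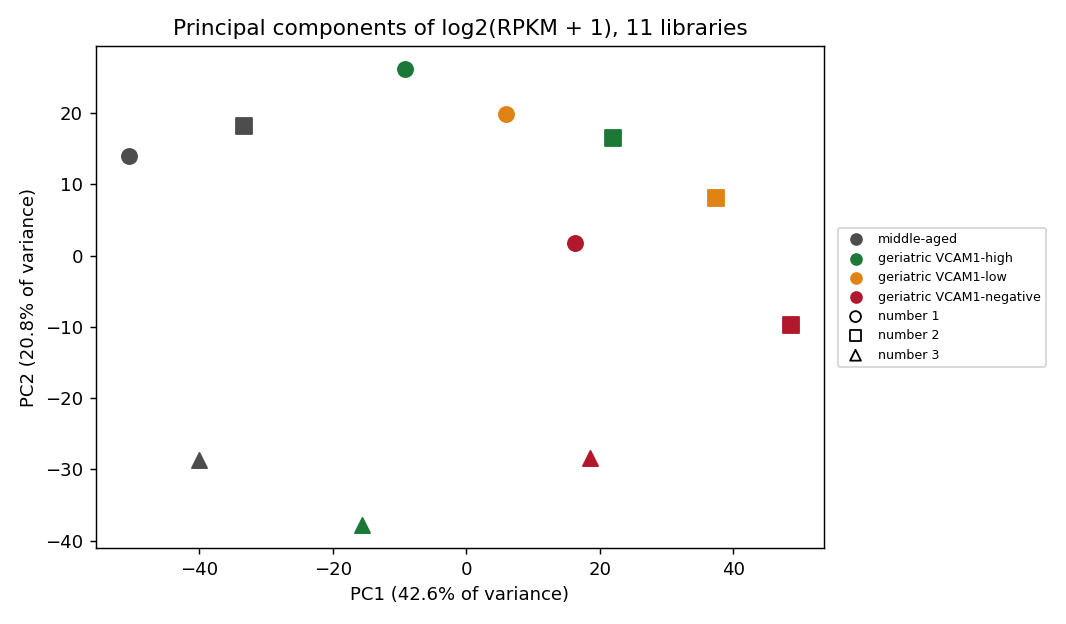
Principal components 1 (42.6% of variance) and 2 (20.8%) of log2(RPKM + 1) in 11 libraries, with color for group and symbol for replicate number. Axes are component scores.

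Vcam1, the gene behind the gates, averaged 303 ± 63.6 RPKM in middle-aged libraries (n = 3), 290 ± 117 in VCAM1-high (n = 3), 146 ± 43.6 in VCAM1-low (n = 2) and 80.3 ± 37.6 in VCAM1-negative (n = 3). By library it read 336, 344 and 230 in middle-aged, 418, 188 and 264 in VCAM1-high, 177 and 115 in VCAM1-low, and 122, 70.4 and 48.6 in VCAM1-negative. The transcript thus orders the geriatric gates by their labels within every replicate number, and the negative gate still holds Vcam1 RNA. Since cells were sorted on the protein, this checks the labels and is no finding. Pax7, the gene whose Cre marked the cells, was low in all groups (6.55, 7.85 and 5.75 RPKM in middle-aged, 5.16, 3.94 and 4.76 in VCAM1-high, 7.36 and 1.97 in VCAM1-low, 4.0, 1.71 and 3.46 in VCAM1-negative). The lysosomal and surface protein gene Cd63 read 1661 to 2727 RPKM in middle-aged and 1373 to 2881 in geriatric libraries. Cd200, for a surface glycoprotein, read 158 to 247 and 122 to 390.

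**Figure D2:**
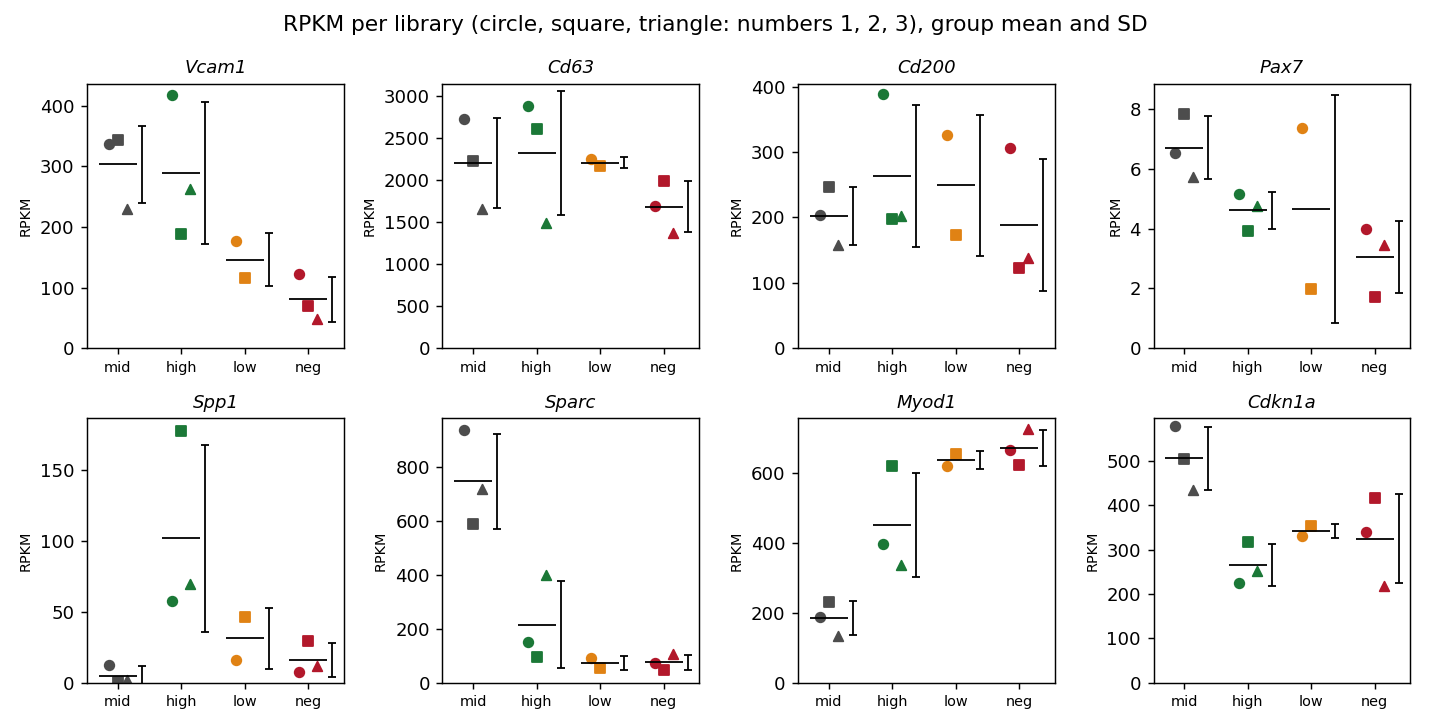
RPKM of 8 genes in each library (points, symbol for replicate number), with group mean and SD, in middle-aged (mid), VCAM1-high, VCAM1-low and VCAM1-negative (neg) libraries.

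The genes used to exclude other cells were not silent. Pecam1 (CD31) read 20.5 RPKM in middle-aged replicate 3 and 10.2 in VCAM1-high replicate 3, against 0.665 to 2.05 in the other libraries of those groups, 4.10 and 8.95 in VCAM1-low, and 10.8, 15.7 and 2.23 in VCAM1-negative. Ly6a (Sca-1) followed the same order within each group: 66.3 in middle-aged replicate 3 against 2.55 and 4.39, 40.4 in VCAM1-high replicate 3 against 2.88 and 7.53, 10.5 and 18.2 in VCAM1-low, and 26.8, 36.2 and 14.3 in VCAM1-negative. Ptprc (CD45) was highest in VCAM1-high replicate 3, at 3.30 RPKM.

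VCAM1-negative libraries differ from VCAM1-high libraries most in transcripts of mature muscle fibers. With replicate number as a block in the 8 geriatric libraries, the skeletal actin gene Acta1 rose by 4.93 ± 0.38 log2 units (limma adjusted p = 0.00449), from 43.0 ± 18.6 to 1858 ± 1422 RPKM (n = 3 and 3). The fast troponin genes Tnnt3 (5.01 ± 0.50, adjusted p = 0.00734) and Tnnc2 (4.93 ± 0.41, adjusted p = 0.00458) rose as far. So did the myosin light chains Myl1 (4.84 ± 0.39, adjusted p = 0.00449) and Mylpf (4.46 ± 0.43, adjusted p = 0.00708). The Z-disc genes Myoz1 (4.77 ± 0.47, adjusted p = 0.00708) and Myot (4.68 ± 0.47, adjusted p = 0.00749) and the muscle creatine kinase gene Ckm (4.71 ± 0.39, adjusted p = 0.00458) rose too. The 12 tested myofibre genes rose as a list without a block (median log2 fold change 3.91, camera adjusted p = 2.05e-32; adjusted p = 0.163 with an estimated correlation). None of the 12 passed over all genes and all 12 did adjusted over the list alone, while 11 passed over all genes with the geriatric block. Without the filter on low values that block model called 0 genes up, so no fiber gene either. Acta1 read 280, 3040 and 2254 RPKM in the VCAM1-negative replicates and at most 109 in every other library.

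In the geriatric block model, Spp1 (osteopontin) fell by 2.62 ± 0.12 log2 units (adjusted p = 0.000427), from 102 to 16.2 RPKM. Dmp1, a mineral-matrix protein gene, fell by 2.91 ± 0.27 (adjusted p = 0.006) and the secreted C1qtnf3 by 2.77 ± 0.18 (adjusted p = 0.00336). Col8a1 (-1.95 ± 0.16, adjusted p = 0.00449), Lrrc17 (-1.83 ± 0.23, adjusted p = 0.0138), the small proteoglycan gene Bgn (-1.63 ± 0.15, adjusted p = 0.00595) and the matrilin gene Matn2 (-1.48 ± 0.23, adjusted p = 0.0204) fell too. Vcam1 itself fell (-1.86 ± 0.19, adjusted p = 0.00749, and 0.112 without a block). The extracellular matrix list fell without a block (19 genes, median -0.60, camera adjusted p = 3.91e-05; adjusted p = 0.741 with an estimated correlation). Of its members 0 passed over all genes, 1 was lower adjusted over the list alone, and 10 were lower with the block. One of these is Sparc (-1.32 ± 0.18, adjusted p = 0.0166), which binds collagen and calcium. Without VCAM1-high replicate 3 the camera adjusted p of this list is 0.175, while without all number-3 libraries it is 0.000101. VCAM1-high replicate 3 also holds the most macrophage transcripts (Lyz2 591 RPKM). Its matrix level is 4.79 log2 units, against 3.42 and 3.33 in VCAM1-high replicates 1 and 2. The fibro-adipogenic progenitor list is higher there too than in those replicates (3.84 and 3.87). The source of these matrix transcripts was not tested. With the block in 11 libraries Dmp1, C1qtnf3, Col8a1, Lrrc17 and Bgn passed too, while Spp1, Matn2 and Sparc did not. Single genes were not followed when the geriatric block model lost a library, although its 137 calls fell to 19 without VCAM1-high replicate 2.

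Stem cell surface markers fell as a list between VCAM1-high and VCAM1-negative (12 genes, Vcam1 included, median -0.40, camera adjusted p = 0.00292; adjusted p = 0.643 with an estimated correlation). None passed over all genes and 1 was lower adjusted over the list alone. With the geriatric block 4 members fell: Vcam1, the M-cadherin gene Cdh15 (-0.79 ± 0.11, adjusted p = 0.0178), the adhesion gene Ncam1 (-0.67 ± 0.10, adjusted p = 0.0184) and the laminin receptor gene Itga7 (-0.94 ± 0.17, adjusted p = 0.031). The myogenic commitment and differentiation list rose (10 genes, median 0.87, camera adjusted p = 0.000375; adjusted p = 0.485 with an estimated correlation). Of its members 0 passed over all genes and 3 were up adjusted over the list alone. With the block the transcription factor gene Mef2c (1.71 ± 0.26, adjusted p = 0.0198), the cardiac actin gene Actc1 (1.40 ± 0.26, adjusted p = 0.0338) and the troponin gene Tnnt2 (1.21 ± 0.25, adjusted p = 0.043) rose. Myf5, which marks committed progenitors, fell (-1.17 ± 0.17, adjusted p = 0.0178). The quiescence and Notch list was not called, though Col5a3 (-1.03 ± 0.13, adjusted p = 0.0137), Col5a1 (-0.60 ± 0.11, adjusted p = 0.0343) and Gas1 (-0.70 ± 0.15, adjusted p = 0.0495) fell with the block. With the block in 11 libraries only Vcam1 and Mef2c of these genes passed. The surface marker call ends without VCAM1-negative replicate 2 (camera adjusted p = 0.051).

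No list of senescence-linked genes was called between VCAM1-negative and VCAM1-high. The senescence regulators (camera adjusted p = 0.571) and the senescence-associated secretory factors (adjusted p = 0.283) were not called. With the geriatric block the lysosomal galactosidase gene Glb1 fell (-0.68 ± 0.15, adjusted p = 0.0499), as did 6 secretory factors. Among these are Spp1, the chemokine genes Cxcl10 (-0.82 ± 0.11, adjusted p = 0.0166) and Ccl2 (-0.61 ± 0.11, adjusted p = 0.0289), and the growth factor binder Igfbp5 (-1.08 ± 0.17, adjusted p = 0.0204). The cell cycle inhibitor Cdkn1a did not pass (0.26 ± 0.16, adjusted p = 0.396), and Cdkn2a stayed at or below 0.555 RPKM in all 11 libraries. Of the proposed markers, Cd200 fell only slightly with the block (-0.53 ± 0.11, adjusted p = 0.0468, and 0.86 without), and Cd63 (-0.43 ± 0.15, adjusted p = 0.138) and Pax7 (-0.51 ± 0.22, adjusted p = 0.210) did not pass. Neither Cd200 nor Glb1 and the secretory factors named above passed with the block in 11 libraries.

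Among stress and cell type lists, immediate early genes (18 genes, median 0.18, camera adjusted p = 0.00252; adjusted p = 0.741 with an estimated correlation) rose in VCAM1-negative. So did the unfolded protein and integrated stress response (12 genes, median 0.23, adjusted p = 0.0146; adjusted p = 0.485 with an estimated correlation). With the geriatric block the stress genes Atf3 (0.59 ± 0.12, adjusted p = 0.0415) and Chac1 (1.29 ± 0.21, adjusted p = 0.0242) rose and the chaperone gene Pdia4 fell (-0.89 ± 0.12, adjusted p = 0.0177). None of these genes passed with the block in 11 libraries. Endothelial (11 genes, median 0.83, adjusted p = 0.00292; adjusted p = 0.741 with an estimated correlation) and erythroid genes (3 genes, median 2.21, adjusted p = 0.0146; adjusted p = 0.668 with an estimated correlation) rose. Mitosis genes (13 genes, median -0.61, adjusted p = 0.0431) and ribosomal protein genes (36 genes, median -0.22, adjusted p = 0.0209) fell (both adjusted p = 0.741 with an estimated correlation). Of these 6 lists 0 members passed over all genes, and adjusted over the list alone only 1 gene of the unfolded protein response did. The mitosis call ends with the block in 11 libraries (adjusted p = 0.177). JAK-STAT feedback (0.0718 without a block, 0.0273 with it in 11 libraries and 0.0339 in 8) and heat shock (0.0270 in 8) gain one. Leaving out VCAM1-negative replicate 1 ends the calls of immediate early (adjusted p = 0.556), unfolded protein (0.350) and endothelial genes (0.090), and leaving out VCAM1-high replicates 1, 2 and 3 in turn ends those of ribosomal (0.824), erythroid (0.146) and mitosis genes (0.903). The 3 VCAM1-high libraries read 10.8, 41.4 and 362 RPKM of Hbb-bs.

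In all, 0 genes passed limma's test between VCAM1-negative and VCAM1-high without a block (lowest adjusted p = 0.0501), and 755 had an unadjusted p under 0.05. In 1314 genes (11.4%) the 3 libraries of one gate lay all above the 3 of the other, against 10% for unchanged groups of independent libraries. With same-numbered libraries correlated as observed, a simulation chosen after seeing the data, the share is 4.94%. Without a block 13 genes passed after rescaling to an equal sum, 16 by the median ratio, 18 at a mean of at least 5 RPKM and 22 with a pseudocount of 0.1. With replicate number as a block 52 genes changed in the 11-library model (32 up, 20 down) and 137 in the 8 geriatric libraries (74 up, 63 down). Without the filter on low values the 137 become 1 (0 up, 1 down). Camera called 10 of 33 lists (6 up, 4 down), and 0 with an estimated correlation. As many lists were called in 7 of the 10 splits of these 6 libraries, the real one included. Without VCAM1-negative replicate 1, the one of its group with the fewest myofibre transcripts, 127 genes passed without a block. The 137 genes fell to 19 without VCAM1-high replicate 2 (6 up, 13 down), 25 without either VCAM1-low library (9 up, 16 down), 39 without VCAM1-negative replicate 2 (18 up, 21 down) and 88 without VCAM1-high replicate 1 (33 up, 55 down). They rose to 215 without VCAM1-negative replicate 1 (146 up, 69 down) and 217 without a number-3 library (162 up, 55 down).

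From middle-aged to geriatric VCAM1-high cells, the complement gene C4b rose by 3.43 ± 0.22 log2 units (adjusted p = 7.63e-05), from 5.62 ± 1.60 to 69.3 ± 9.70 RPKM (n = 3 and 3). The protease inhibitor genes Serpina3n rose by 3.50 ± 0.36 (adjusted p = 0.00211) and Serpina3m by 3.88 ± 0.55 (adjusted p = 0.0142). Cfd (complement factor D, also named adipsin) rose from at most 0.0723 RPKM in any middle-aged library to 21.6, 48.6 and 293 (6.05 ± 0.74, adjusted p = 0.00535). Spp1 (4.56 ± 0.78, adjusted p = 0.0313), the iron-siderophore binder Lcn2 (3.43 ± 0.56, adjusted p = 0.0266), the kininogen gene Kng2 (2.71 ± 0.39, adjusted p = 0.0165) and the inhibitory receptor gene Btla (2.61 ± 0.30, adjusted p = 0.0052) rose too. The neuropeptide gene Gal (galanin) fell most, by 2.80 ± 0.34 (adjusted p = 0.00535), from 2883 ± 367 to 442 ± 204 RPKM.

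Other genes that fell most from middle-aged to VCAM1-high are the tubulin gene Tubb4a (-2.06 ± 0.32, adjusted p = 0.0237), the secreted protease Htra1 (-1.94 ± 0.34, adjusted p = 0.0368), and the mitochondrial arginase Arg2 (-1.87 ± 0.19, adjusted p = 0.00211). The receptor kinase Ret (-1.58 ± 0.28, adjusted p = 0.0373), the growth factors Mdk (-1.47 ± 0.26, adjusted p = 0.0368) and Igf1 (-1.34 ± 0.25, adjusted p = 0.0418), and Tcim (-1.35 ± 0.25, adjusted p = 0.0399) fell as well. Vcam1 (-0.12 ± 0.37, adjusted p = 0.900), Pax7 (-0.45 ± 0.35, adjusted p = 0.558), Cd63 (0.05 ± 0.27, adjusted p = 0.946) and Cd200 (0.32 ± 0.39, adjusted p = 0.718) did not pass. The commitment factor Myod1 (1.27 ± 0.25, adjusted p = 0.0542) and Cdkn1a (-0.94 ± 0.24, adjusted p = 0.109) passed only with the replicate block (0.0142 and 0.0236). In all 49 genes rose and 13 fell (lowest adjusted p = 7.63e-05), and the libraries of the 2 groups did not overlap in 2336 genes (20.2%, against 10% for independent libraries and 5.86% with numbers correlated as observed). A model of only the 2 groups gave 14 genes and no filter on low values 16. With the replicate block 203 rose and 116 fell, all 62 among them. Leaving out 1 library gave 19, 17 and 35 genes without middle-aged replicates 1, 2 and 3, 33, 18 and 214 without VCAM1-high 1, 2 and 3, and 38 without either VCAM1-low library. It gave 36, 38 and 26 without VCAM1-negative 1, 2 and 3. Cfd, Serpina3n, C4b, Btla, Gal and Arg2 passed in each of these omissions, though Cfd did not in the model of only the 2 groups (adjusted p = 0.0558). Serpina3m did not pass without middle-aged replicate 1 (adjusted p = 0.075), nor the other 9 changed genes named here without VCAM1-high replicate 2 (0.083 for Kng2 to 0.195 for Tcim). Of the 11 omissions, Htra1, Ret and Igf1 passed in 1, Tcim in 2 and Mdk in 3. Spp1, Lcn2 and Tubb4a passed in 6 and Kng2 in 7.

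Immune signalling lists rose from middle-aged to VCAM1-high. These are the interferon response (15 genes, median 0.74, camera adjusted p = 0.000415; adjusted p = 0.622 with an estimated correlation) and MHC class I presentation (10 genes, median 0.65, adjusted p = 3.20e-05; 0.528 with an estimated correlation). JAK-STAT feedback genes rose too (8 genes, median 0.46, adjusted p = 0.000415; 0.528 with an estimated correlation). Adjusted over the list alone 8, 6 and 3 members were up, and over all genes only the cytokine feedback gene Cish (1.07 ± 0.15, adjusted p = 0.0114). TGF-beta and BMP targets rose as well (10 genes, median 0.48, adjusted p = 0.0292; 0.622 with an estimated correlation, and 0.0649 with the replicate block). Of them the inhibitory gene Smad6 passed over all genes (1.24 ± 0.21, adjusted p = 0.0313) and 2 members over the list alone. Without middle-aged replicate 1 the TGF-beta call ends (adjusted p = 0.205), and without VCAM1-high replicate 2 Smad6 does not pass (0.171). Smad6 passed in only 2 of the 11 omissions of 1 library. Cish does not pass in a model of only the 2 groups (0.0993) or without the number-3 libraries (0.0638).

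Structural and metabolic lists fell from middle-aged to VCAM1-high. The extracellular matrix list fell (19 genes, median -0.78, camera adjusted p = 1.06e-05; adjusted p = 0.622 with an estimated correlation). Of its members 0 passed over all genes and 1 was lower over the list alone. Quiescence and Notch genes (19 genes, median -0.52, adjusted p = 0.00264; 0.622 with an estimated correlation) and oxidative phosphorylation (18 genes, median -0.31, adjusted p = 0.000556; 0.736 with an estimated correlation) fell. Ribosomal proteins (36 genes, median -0.22, adjusted p = 0.000303) and myofibres (12 genes, median -0.87, adjusted p = 0.0153) fell too (both adjusted p = 0.847 with an estimated correlation). None of these 4 lists had a member past either count. Calls end for oxidative phosphorylation without middle-aged replicate 1 (adjusted p = 0.106), for ribosomal proteins without VCAM1-high replicate 3 (0.450) and for myofibres without VCAM1-high replicate 1 (0.111).

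Some markers of other cells rose beside these genes. Neutrophil (6 genes, median 1.64, camera adjusted p = 0.00264; adjusted p = 0.622 with an estimated correlation) and adipocyte lists (4 genes, median 1.56, adjusted p = 0.00723; 0.622 with an estimated correlation) rose from middle-aged to VCAM1-high. Over the list alone 4 and 2 members were up, and over all genes only Cfd. The sodium channel gene Scn7a, of the Schwann cell list (2.32 ± 0.28, adjusted p = 0.00535), the B-cell receptor gene Cd79a (1.41 ± 0.26, adjusted p = 0.0412) and the tendon regulator Scx (1.14 ± 0.21, adjusted p = 0.041) rose. Lyz2 reached 591 RPKM, S100a9 21.8 and Adipoq 14.6 in VCAM1-high replicate 3. Camera called 11 of 33 lists (6 up, 5 down), and 0 with an estimated correlation. As many lists were called in 6 of the 10 splits of these 6 libraries, the real one included. The neutrophil call ends without VCAM1-high replicate 3 (adjusted p = 0.064), and without VCAM1-high replicate 2 Cd79a (0.204) and Scx (0.195) do not pass. Over the 11 omissions of 1 library Cd79a passed in 2 and Scx in 3. The senescence-associated secretory list was not called (30 genes, adjusted p = 0.0740, and 0.039 with the replicate block), nor were senescence regulators (0.867) or p53 targets (0.317).

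From middle-aged to VCAM1-negative cells the change is wider: 425 genes rose and 463 fell. Which direction holds more genes depends on the setting, with 581 up and 442 down at an equal sum, 511 and 394 without VCAM1-negative replicate 1, and 309 and 194 without the number-3 libraries. Cfd rose most (6.40 ± 0.74, adjusted p = 0.00217), to 76.0, 158 and 54.6 RPKM, followed by haptoglobin, Hp (5.29 ± 1.08, adjusted p = 0.0151), and the carbonic anhydrase gene Car3, abundant in muscle fibers and in adipocytes (4.53 ± 0.76, adjusted p = 0.00843). Genes of muscle fibers follow: Myot (4.44 ± 0.63, adjusted p = 0.00432), Hspb7 (4.18 ± 0.78, adjusted p = 0.0107), Tnnt3 (4.15 ± 0.76, adjusted p = 0.0104), Acta1 (4.05 ± 0.81, adjusted p = 0.0141) and Tcap (3.90 ± 0.74, adjusted p = 0.0112). The myofibre list rose (12 genes, median 3.22, camera adjusted p = 1.30e-07; adjusted p = 0.539 with an estimated correlation). Of its members 9 were up over all genes and 11 over the list alone, among them Myh4 (3.44 ± 0.61, adjusted p = 0.00975), Mylpf (3.68 ± 0.69, adjusted p = 0.011) and Tnnc2 (3.43 ± 0.67, adjusted p = 0.0129). Without VCAM1-negative replicate 2, Hp (adjusted p = 0.061), Acta1 (0.056) and Tnnc2 (0.050) do not pass. Without the number-3 libraries Hspb7 (0.0535), Tnnt3 (0.0619), Tcap (0.0672) and Mylpf (0.0747) do not.

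Matrix genes fell from middle-aged to VCAM1-negative. Col3a1 fell by 4.25 ± 0.77 log2 units (adjusted p = 0.0104), from a mean of 310 to 18.4 RPKM (n = 3 and 3). Sparc fell by 3.33 ± 0.46 (adjusted p = 0.00393), the matrix protein gene Dpt by 3.14 ± 0.59 (adjusted p = 0.0107) and C1qtnf3 by 4.42 ± 0.63 (adjusted p = 0.00417). The extracellular matrix list fell (19 genes, median -1.38, camera adjusted p = 1.30e-07; adjusted p = 0.539 with an estimated correlation). Of its members 11 were down over all genes and 15 over the list alone, among them the basement membrane gene Col4a2 (-1.60 ± 0.33, adjusted p = 0.0152) and the fibrillin gene Fbn1 (-1.27 ± 0.27, adjusted p = 0.0173). Nrep (-4.60 ± 0.73, adjusted p = 0.0071), Itm2a (-3.49 ± 0.40, adjusted p = 0.00216), Otoa (-3.08 ± 0.57, adjusted p = 0.0104) and Gal (-3.04 ± 0.34, adjusted p = 0.00216) fell as well. Without VCAM1-negative replicate 2, Col4a2 (adjusted p = 0.062) and Fbn1 (0.071) do not pass.

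Stem cell markers fell and a commitment factor rose. Surface markers fell from middle-aged to VCAM1-negative (12 genes, median -0.76, camera adjusted p = 0.0157; adjusted p = 0.539 with an estimated correlation). By either count 5 members were down, among them Vcam1 (-1.98 ± 0.37, adjusted p = 0.0104), Itgb1 (-0.72 ± 0.18, adjusted p = 0.0257), the quiescence-linked receptor Calcr (-1.0 ± 0.27, adjusted p = 0.0349) and Itga7 (-1.36 ± 0.39, adjusted p = 0.0426). Quiescence and Notch genes fell (19 genes, median -0.93, adjusted p = 0.0144; 0.539 with an estimated correlation), with 4 down and 1 up over all genes and 9 down and 1 up over the list alone. Col5a3 (-2.33 ± 0.53, adjusted p = 0.0215), Gas1 (-2.45 ± 0.57, adjusted p = 0.0221) and Col5a1 (-1.38 ± 0.37, adjusted p = 0.0338) fell and the Notch target Hes1 rose (1.05 ± 0.26, adjusted p = 0.0254). Of the myogenic list (10 genes, adjusted p = 0.0540) Myod1, the commitment factor, rose from 185 ± 48.1 to 670 ± 52.1 RPKM (1.88 ± 0.25, adjusted p = 0.00344), as did Myf6 (1.99 ± 0.50, adjusted p = 0.0289). Pax7 passed only with the replicate block (-0.97 ± 0.35, adjusted p = 0.081, and 0.0321 with the block). Same-numbered libraries of these groups hardly deviate together (correlations -0.02, 0.03 and 0.08), so a block has little ground in this comparison. Cd63 (-0.38 ± 0.27, adjusted p = 0.348) and Cd200 (-0.21 ± 0.39, adjusted p = 0.737) did not pass. Calls end without VCAM1-negative replicate 2 for Itga7 (adjusted p = 0.155), Itgb1 (0.097), Gas1 (0.088), Hes1 (0.098), Col5a3 (0.0808) and Col5a1 (0.120), without replicate 3 for Calcr (0.088), without middle-aged replicate 1 for Myf6 (0.084), and without the number-3 libraries for Vcam1 (0.0521).

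Cytokine feedback and interferon genes rose from middle-aged to VCAM1-negative. The JAK-STAT feedback list rose (8 genes, median 0.65, camera adjusted p = 0.00104; adjusted p = 0.539 with an estimated correlation). Up over all genes were 4 members and over the list alone 5. They include the oncostatin M receptor Osmr (1.97 ± 0.33, adjusted p = 0.0085), Socs3 (1.10 ± 0.19, adjusted p = 0.00922), Cish (1.05 ± 0.15, adjusted p = 0.00393) and Stat3 (0.74 ± 0.19, adjusted p = 0.0295). The interferon list rose (15 genes, median 0.73, adjusted p = 0.00614; 0.539 with an estimated correlation), with 5 up and 1 down over all genes and 9 up and 1 down over the list alone. Among these are Rsad2 (1.63 ± 0.40, adjusted p = 0.0254) and Irf7 (0.73 ± 0.17, adjusted p = 0.0222). MHC class I genes rose (10 genes, median 0.56, adjusted p = 0.0180; 0.539 with an estimated correlation). The activator Nlrc5 was up over all genes (1.41 ± 0.27, adjusted p = 0.0126) and 7 members over the list alone. TGF-beta and BMP targets rose (10 genes, median 0.42, adjusted p = 0.0366; 0.539 with an estimated correlation, and 0.0573 with the replicate block). By either count 3 members were up, Smad6 (1.39 ± 0.21, adjusted p = 0.00578) and Smad7 (1.15 ± 0.26, adjusted p = 0.0194) among them. Immediate early genes rose (18 genes, median 0.31, adjusted p = 0.0366; 0.748 with an estimated correlation), 2 by either count: Atf3 (1.06 ± 0.19, adjusted p = 0.00998) and Egr2 (0.89 ± 0.21, adjusted p = 0.0217). Calls end without middle-aged replicate 1 for MHC class I (adjusted p = 0.096) and Smad7 (0.064), without VCAM1-negative replicate 1 for TGF-beta (0.162) and immediate early genes (0.462), and without VCAM1-negative replicate 2 for Stat3 (0.096), Rsad2 (0.099), Irf7 (0.090) and Nlrc5 (0.055). Egr2 does not pass without middle-aged replicate 3 (0.0659).

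Growth and energy lists fell from middle-aged to VCAM1-negative: ribosomal proteins (36 genes, median -0.45, camera adjusted p = 7.22e-05; adjusted p = 0.748 with an estimated correlation) and oxidative phosphorylation (18 genes, median -0.50, adjusted p = 0.00866; 0.738 with an estimated correlation). Mitosis genes fell too (13 genes, median -0.84, adjusted p = 0.0327; 0.775 with an estimated correlation, and 0.0732 with the replicate block). One ribosomal gene, Rps9, passed over all genes (-0.68 ± 0.21, adjusted p = 0.0484) and 0 over the list alone, and the other 2 lists had 0 by either count. Adipocyte genes rose (4 genes, median 1.80, adjusted p = 0.0157; 0.539 with an estimated correlation), 2 by either count: Cfd and the adipokine gene Adipoq (2.74 ± 0.58, adjusted p = 0.0165). Without middle-aged replicate 1 the oxidative phosphorylation (adjusted p = 0.116) and mitosis calls (0.340) end, and without VCAM1-negative replicate 2 Adipoq (0.068) and Rps9 (0.152) do not pass. Rps9 passed in only 1 of the 11 omissions of 1 library.

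**Figure D3:**
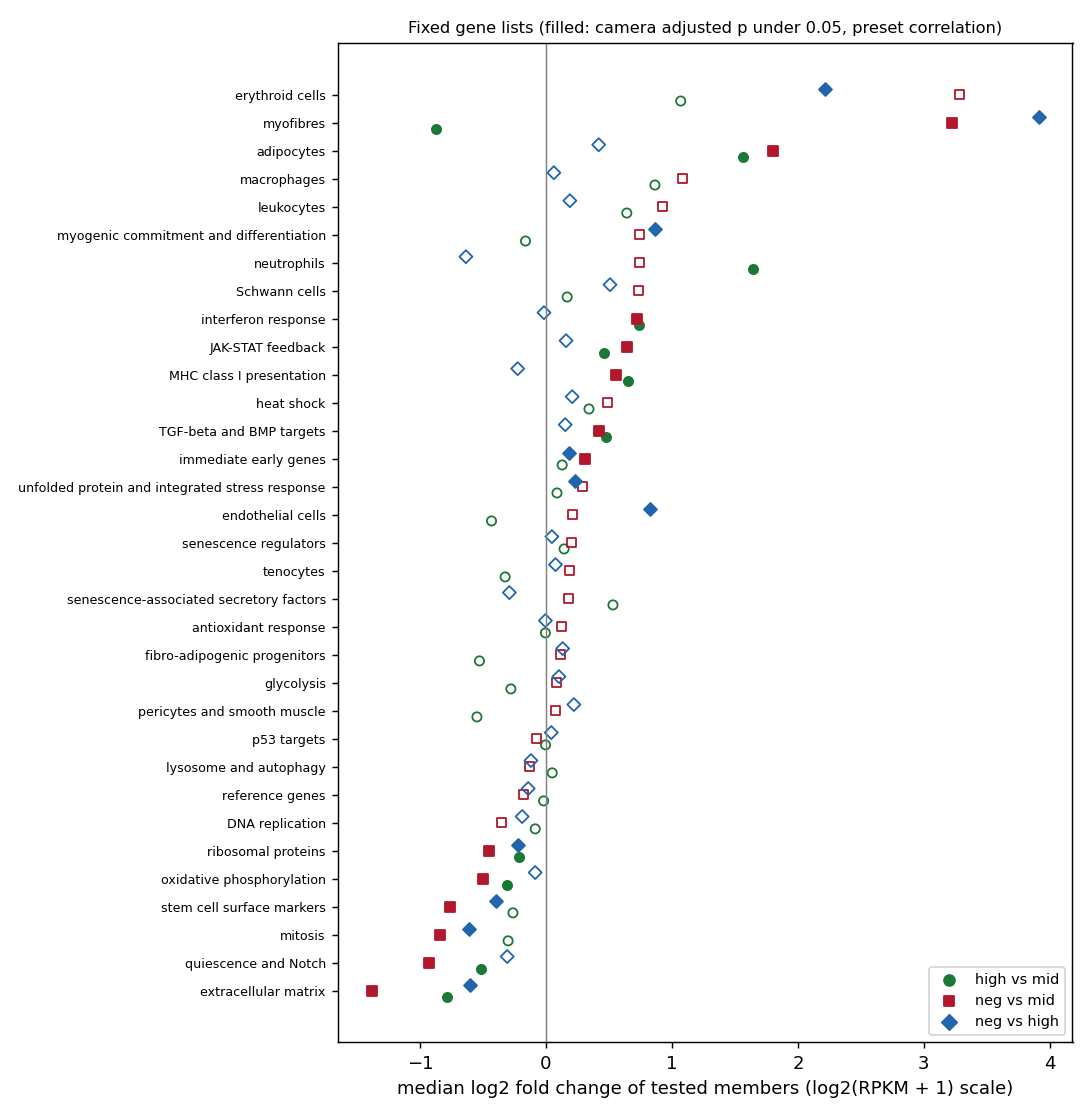
Median log2 fold change (horizontal axis) of the tested members of 33 gene lists in 3 comparisons. Filled symbols passed camera with the preset correlation.

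Senescence lists were not called between middle-aged and VCAM1-negative: regulators at camera adjusted p = 0.711, secretory factors at 0.487 and p53 targets at 0.931. Over all genes 1 regulator rose, the cell cycle inhibitor Cdkn2d (1.07 ± 0.29, adjusted p = 0.0358), and 1 fell, Trp53 (-0.68 ± 0.18, adjusted p = 0.0323), with 3 up and 3 down over the list alone. Secretory factors past the test include Csf1 (1.14 ± 0.29, adjusted p = 0.0295) and Ccl8 (1.51 ± 0.45, adjusted p = 0.0479), which rose, and Cxcl2, which fell (-1.04 ± 0.31, adjusted p = 0.0477). Cdkn1a read 435 to 578 RPKM in middle-aged and 217 to 416 in VCAM1-negative libraries, and passed only with the replicate block (-0.68 ± 0.24, adjusted p = 0.0778, and 0.0217 with the block). As for Pax7, that block has little ground between these groups. Without VCAM1-negative replicate 2, Cdkn2d (adjusted p = 0.127), Trp53 (0.115), Csf1 (0.111) and Ccl8 (0.152) do not pass, nor does Cxcl2 without replicate 3 (0.133). Over the 11 omissions of 1 library Cxcl2 passed in 1 and Ccl8 in 3.

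Between middle-aged and VCAM1-negative, single members passed in lists that were not called. The glutathione and quinone enzymes Gclc (1.62 ± 0.29, adjusted p = 0.00965) and Nqo1 (1.11 ± 0.26, adjusted p = 0.0221) of the antioxidant list rose. So did the stress gene Chac1 (2.14 ± 0.29, adjusted p = 0.00393), the autophagy gene Map1lc3b (1.12 ± 0.23, adjusted p = 0.0153) and the polymerase subunit Polr2a (1.42 ± 0.28, adjusted p = 0.0129). Of other cell types' genes Scn7a (2.28 ± 0.28, adjusted p = 0.0025), Cd79a (1.53 ± 0.26, adjusted p = 0.00876), Scx (1.18 ± 0.21, adjusted p = 0.00972) and the fibroblast proteoglycan Dcn (2.85 ± 0.80, adjusted p = 0.0401) rose. Cd79a is the only gene of the B-cell list that passed the filter. Col3a1 and Dpt, on the same list as Dcn, fell. Of the pericyte and smooth muscle list Tagln fell (-2.51 ± 0.48, adjusted p = 0.0112) and Abcc9 rose (1.04 ± 0.27, adjusted p = 0.0297). The lysosomal protease gene Ctsz (-0.99 ± 0.27, adjusted p = 0.0388), the ribonucleotide reductase gene Rrm2 (-1.13 ± 0.30, adjusted p = 0.0338) and Pdia4 (-1.47 ± 0.39, adjusted p = 0.0336) fell. The lists uncalled here also include DNA replication, heat shock, glycolysis, reference genes, leukocytes, macrophages, neutrophils, endothelial cells, fibro-adipogenic progenitors, tenocytes, pericytes, Schwann cells and erythroid cells. The 20 camera adjusted p-values run from 0.0540 to 0.989. Calls end without VCAM1-negative replicate 2 for Nqo1 (adjusted p = 0.087), Map1lc3b (0.063), Pdia4 (0.126), Rrm2 (0.0984) and Ctsz (0.145), and without middle-aged replicate 1 for Dcn (0.120) and Abcc9 (0.0975). Without the number-3 libraries Gclc (0.0678) and Polr2a (0.0618) do not pass.

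Of the 888 genes changed between middle-aged and VCAM1-negative (lowest adjusted p = 3.56e-05) all pass with the replicate block too. In 4511 genes (39.0%) the libraries of the 2 groups did not overlap, against 10% for independent libraries and 9.68% with numbers correlated as observed. Camera called 13 of 33 lists (7 up, 6 down), and 0 with an estimated correlation. As many lists were called in 4 of the 10 splits of these 6 libraries, the real one included. The 888 fell to 298 without VCAM1-negative replicate 2, to 401 without middle-aged replicate 1, to 472 without the filter on low values, and to 503 without the 3 number-3 libraries.

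**Figure D4:**
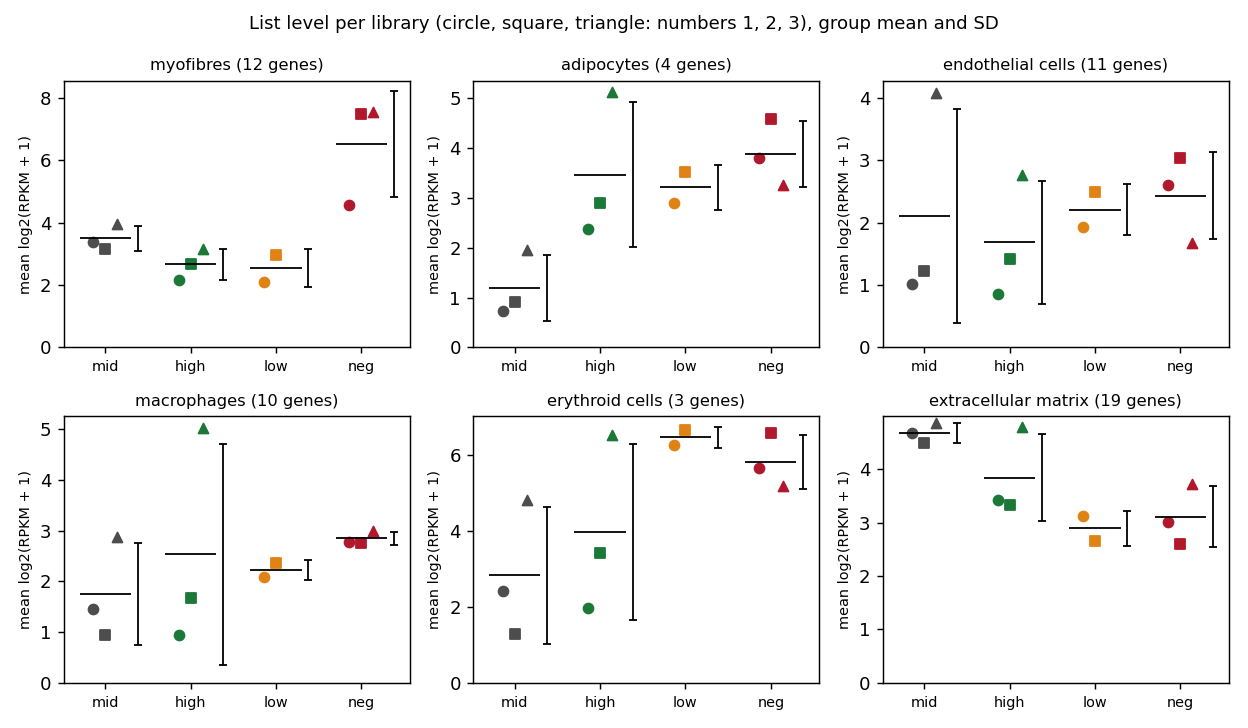
Mean log2(RPKM + 1) of 6 gene lists in each library (points, symbol for replicate number), with group mean and SD, by group on the horizontal axis.

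VCAM1-low libraries (n = 2) also differ from middle-aged cells. Myod1 rose from middle-aged to VCAM1-low by 1.81 ± 0.28 (adjusted p = 0.0138), Serpina3m by 4.13 ± 0.61 (adjusted p = 0.0124), Cfd by 5.29 ± 0.83 (adjusted p = 0.0139) and the retinoic acid hydroxylase Cyp26a1 by 4.39 ± 1.06 (adjusted p = 0.0465). Nrep (-4.73 ± 0.82, adjusted p = 0.0196), Col3a1 (-4.61 ± 0.87, adjusted p = 0.0246), C1qtnf3 (-3.98 ± 0.70, adjusted p = 0.0197) and Sparc (-3.36 ± 0.52, adjusted p = 0.0138) fell. In all 213 rose and 175 fell (lowest adjusted p = 0.000144), and with the replicate block 324 and 447 (360 shared). The libraries of the 2 groups did not overlap in 5183 genes (44.8%, against 20% for independent libraries and 18.8% with numbers correlated as observed). Without VCAM1-low replicate 2 only 1 gene passed and without replicate 1 22, and these 8 genes had an adjusted p of 0.199 to 0.351 without replicate 2. Omitting other libraries gave 66, 125 and 134 (middle-aged), 173, 541 and 603 (VCAM1-high), and 238, 380 and 282 (VCAM1-negative). No filter on low values gave 81, and omitting the number-3 libraries 228.

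Between middle-aged and VCAM1-low camera called 13 lists. The matrix list (median -1.51, camera adjusted p = 1.52e-08), surface markers (-0.93, 0.0236), quiescence and Notch (-0.83, 0.0159), oxidative phosphorylation (-0.49, 0.00173) and ribosomal proteins (-0.25, 0.0348) fell. Interferon response (0.93, 0.000694), MHC class I (0.76, 0.000694), JAK-STAT feedback (0.61, 0.000276), TGF-beta targets (0.47, 0.0123), immediate early genes (0.45, 0.000694), heat shock (1.0, 0.0478, and 0.078 with the replicate block), adipocytes (1.17, 0.0371) and erythroid cells (3.98, 0.0200) rose. With an estimated correlation their adjusted p runs from 0.527 to 0.806. Past the test over all genes were 6 matrix genes (16 over the list alone), 2 interferon (9), 2 MHC class I (5), 2 TGF-beta (4) and 3 JAK-STAT genes (3), among them Cish (1.19 ± 0.16, adjusted p = 0.0111) and Osmr (1.94 ± 0.37, adjusted p = 0.0271). Passing members of other called lists include the surface marker Itgb1, Col5a3 (quiescence), Atf3 (immediate early) and Cfd (adipocytes). Calls end without middle-aged replicate 1 for ribosomal proteins (0.724) and adipocytes (0.0957), without middle-aged replicate 2 for surface markers (0.0615), without VCAM1-low replicate 1 for TGF-beta (0.0827), erythroid (0.0677) and heat shock genes (0.878), and without VCAM1-low replicate 2 for quiescence genes (0.0772).

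Within the geriatric gates 0 genes passed limma's test between VCAM1-low and VCAM1-high (lowest adjusted p = 0.982, 337 at unadjusted p under 0.05, and 1968 or 17.0% with no overlap, against 20% for independent libraries and 13.2% with numbers correlated as observed). Between VCAM1-negative and VCAM1-low 0 passed as well (lowest adjusted p = 0.184, 217 at unadjusted p under 0.05, and 1257 or 10.9% with no overlap, against 20% and 12.3%). With the geriatric block 1 gene passed in the former (adjusted p = 0.0200), and without VCAM1-negative replicate 1 117 did in the latter. From VCAM1-high to VCAM1-low camera called a fall of matrix genes (median -0.76, adjusted p = 1.85e-08; 0.588 with an estimated correlation) and surface markers (-0.54, 0.00435; 0.588). It called a rise of immediate early genes (0.34, 7.33e-10; 0.466), heat shock (0.53, 0.00023; 0.634), the unfolded protein response (0.29, 0.000489; 0.422), JAK-STAT feedback (0.23, 0.00771; 0.466), endothelial (0.56, 0.00418; 0.810) and erythroid genes (2.91, 0.00023; 0.466). None of their members passed over all genes. Calls end without VCAM1-low replicate 1 for heat shock (adjusted p = 0.937) and the unfolded protein response (0.257), and without replicate 2 for surface markers (0.146), JAK-STAT (0.444) and endothelial genes (0.284). VCAM1-low has no number-3 library, so comparisons with it without a block mix group with replicate number. By number the matrix level is 3.42, 3.33 and 4.79 log2 units in VCAM1-high and 3.12 and 2.66 in VCAM1-low. Heat shock reads 9.22, 8.34 and 7.60 against 9.81 and 8.26. The JAK-STAT call ends without the number-3 libraries (camera adjusted p = 0.104).

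From VCAM1-low to VCAM1-negative, myofibre genes (median 4.20, camera adjusted p = 5.29e-49; adjusted p = 0.0527 with an estimated correlation), the myogenic list (1.83, 5.72e-07; 0.192), glycolysis (0.23, 2.38e-05; 0.731) and leukocyte genes (0.83, 0.0278; 0.731) rose. Ribosomal proteins (-0.18, 9.68e-06), immediate early genes (-0.16, 0.00419), heat shock (-0.24, 0.0278) and MHC class I genes (-0.17, 0.0278) fell, each at 0.731 with an estimated correlation. All 12 myofibre genes and 2 myogenic genes were up adjusted over the list alone, and 0 over all genes. With the replicate block the calls of leukocytes (adjusted p = 0.587), ribosomal proteins (0.133), immediate early genes (0.192) and heat shock (0.259) end, as does that of MHC class I in the 8 geriatric libraries (0.120). Left-out libraries that end calls are VCAM1-low replicate 1 for leukocytes (0.395) and ribosomal proteins (0.099), VCAM1-low replicate 2 for MHC class I (0.527), and VCAM1-negative replicate 3 for immediate early genes (0.908) and heat shock (0.989).

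On the genes that changed between VCAM1-high and VCAM1-negative with the geriatric block, the VCAM1-low libraries split by direction. On the 74 that rose, fiber genes among them, the median position on a scale from 0 (VCAM1-high) to 1 (VCAM1-negative) is -0.088 in replicate 1 and 0.082 in replicate 2. On the 63 that fell, matrix genes among them, it is 0.63 and 1.20. Over both it is 0.118 and 0.314. The ends of the scale are means over all 3 libraries of each gate, while VCAM1-low has no number-3 library. The position thus mixes gate with replicate number. The genes come from a model that holds the VCAM1-low libraries too, no test of the position was made, and n is 2.

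Fold changes of VCAM1-high and VCAM1-negative against middle-aged cells correlate at 0.805 over all tested genes, against 0.503 simulated for groups without any change, since both share the middle-aged libraries (covariance 0.247 against 0.0530). That simulation takes libraries as independent. With same-numbered libraries correlated as observed, an alternative chosen after seeing the data, the simulated correlation is 0.686 (covariance 0.0571). The sign was the same in 84.5% of genes, against 66.6% and 73.9% in the 2 simulations. Of the changed genes 42 rose in both comparisons, Cfd and C4b among them, 13 fell in both, Gal among them, and 0 moved in opposite directions. Independent lists of these sizes would share 1.80 and 0.520, a value that leaves out the shared middle-aged libraries, so part of the overlap may come from them. The F test over the 4 groups passed 384 genes (3.32%), and 2025 with the replicate block. Leaving out 1 library moved the F test's count to 39, 67 and 96 (middle-aged 1 to 3), 164, 474 and 614 (VCAM1-high), 201 and 117 (VCAM1-low) and 405, 129 and 121 (VCAM1-negative). It was 39 without the filter on low values and 98 without the number-3 libraries.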

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

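Of the tests in this part, those on fiber RNA and differentiating cells in the VCAM1-negative gate were chosen only after the fiber transcripts were seen. Camera between the geriatric gates, with and without the replicate block, singled out 3 gene lists whose median log2 fold changes against middle-aged libraries also have opposite signs: endothelial cells (-0.43 in VCAM1-high and 0.21 in VCAM1-negative), myofibres (-0.87 and 3.22) and myogenic commitment and differentiation (-0.16 and 0.74). The calls that picked them (adjusted p = 0.00292, 2.05e-32 and 0.000375) are thus no further evidence, and with an estimated correlation none passes (0.741, 0.163 and 0.485). Against middle-aged libraries only the myofibre list was called in both gates, while endothelial (adjusted p = 0.171 and 0.659) and myogenic genes (0.919 and 0.0540) were called in neither, so their opposite signs were not shown.

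RNA or fragments of mature fibers carried into the VCAM1-negative sort would raise genes of mature fibers and leave genes of early differentiation behind. The median log2 fold change of the early genes lies 3.30 below that of the myofibre list (0.62 against 3.91, a difference of -3.30), with Acta1 at 280, 3040 and 2254 RPKM, but 3 of the 5 early genes stay under 5 RPKM, where the added 1 RPKM shrinks their fold changes, so the gap does not decide it. Differentiating cells in the gate would raise the early genes, and 0 of 5 reached a log2 fold change of 1 at unadjusted p under 0.05 with the geriatric block, but only 2 of the 5 reach 5 RPKM, a bound set after the values were seen, so this stays open too. Myog averaged 25.3 RPKM in VCAM1-high and 29.6 in VCAM1-negative. Mymk (3.07 to 5.39, log2 fold change 0.77) and Myh8 (0.0338 to 1.16, 0.96) met the p bound and missed only the fold bound. Their unadjusted limma p with the block was 0.0244 and 0.00987, and their adjusted p 0.153 and 0.0970. The YFP gate would remove unlabelled fibers, while none of the 3 proteins used to exclude cells (Sca-1, CD31, CD45) marks fibers. Whether fibers of these mice carried the label was not tested.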

How the results depend on the processing

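The cause of the changes given here was not tested, except where fewer libraries or more tested genes show it. Leaving out 1 library gave 0 to 127 genes between VCAM1-negative and VCAM1-high, 17 to 214 between VCAM1-high and middle-aged, 298 to 951 between VCAM1-negative and middle-aged, 0 to 117 between VCAM1-negative and VCAM1-low, 1 to 603 between VCAM1-low and middle-aged, 39 to 614 in the F test and 19 to 217 for the geriatric block. Lists called ran from 6 to 12, 10 to 15 and 9 to 19 in the 3 main comparisons, the correlation of fold changes from 0.720 to 0.838, and Vcam1 between VCAM1-negative and VCAM1-high from -2.21 to -1.56 (adjusted p = 0.0099 without VCAM1-negative replicate 1). With 1 VCAM1-low library left, it is assumed to vary like the other groups.

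Between VCAM1-negative and VCAM1-high, where 0 genes passed, a pseudocount of 0.1 gave 22, a mean of at least 5 RPKM 18, an equal sum 13, the median ratio 16, and leaving out the number-3 libraries (chosen after seeing the data) 2. Without a filter on low values, which tests more genes, the counts were 16 (VCAM1-high against middle-aged), 472 (VCAM1-negative against middle-aged), 81 (VCAM1-low against middle-aged), 39 (F test) and 1 (geriatric block). Only the 2 groups compared gave 14 between VCAM1-high and middle-aged. Without the number-3 libraries the counts were 503 (VCAM1-negative against middle-aged), 228 (VCAM1-low against middle-aged), 98 (F test) and 217 (geriatric block), with 16 lists between VCAM1-negative and VCAM1-high and 23 between VCAM1-negative and middle-aged. An estimated correlation left 0 lists in each comparison.

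The replicate block gave 52 genes between VCAM1-negative and VCAM1-high (137 in the 8 geriatric libraries), 319 between VCAM1-high and middle-aged, 771 between VCAM1-low and middle-aged, 1 between VCAM1-low and VCAM1-high (geriatric libraries) and 2025 in the F test. Vcam1 between VCAM1-negative and VCAM1-high passed with the block (-1.86, adjusted p = 0.0187 in 11 and 0.00749 in 8 libraries). The block also called lists not called without it: between VCAM1-low and VCAM1-high oxidative phosphorylation and, in 8 libraries, ribosomal proteins, and between VCAM1-low and middle-aged secretory factors, macrophages and neutrophils. Between VCAM1-negative and VCAM1-low it called neutrophils and, in 11 libraries, erythroid cells, and in 8 libraries surface markers, quiescence, secretory factors, oxidative phosphorylation and matrix. In these 8-library calls the median turned, for matrix from 0.152 without a block to -0.212 (adjusted p = 0.00336), for surface markers from 0.0271 to -0.138 and for quiescence from 0.0210 to -0.172. Between VCAM1-negative and VCAM1-high it also called falls of Dpt, Eno1, Col5a2, Col3a1, Ctsz, Ifi27, Ccn2 and Psmb9 in 8 libraries (adjusted p 0.00449 to 0.0442). Apart from these and the calls given with the results, the block changed no other call among the named genes and lists followed here. Between VCAM1-negative and middle-aged it gave 1105 changed genes (518 up, 587 down), the 888 called without a block among them.

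Among named genes and lists called without a block, directions reversed in 12 values, none past a threshold in the changed setting. Between VCAM1-high and middle-aged, Cd63 reversed by the median ratio (-0.0196) and without middle-aged replicate 3 (-0.139) or VCAM1-high replicate 1 (-0.132) or 2 (-0.0606), and Vcam1 without VCAM1-high replicate 2 (0.152). Leaving out 1 library moved them from -0.139 to 0.343 and from -0.421 to 0.152. Cd200 between VCAM1-negative and middle-aged ran from -0.619 to 0.0395 (without VCAM1-negative replicate 2). Between VCAM1-negative and VCAM1-high the mitosis median ran from -1.01 to -0.0234 (its camera direction reversed without VCAM1-high replicate 3) and was 0.0155 without the number-3 libraries, and the ribosomal median ran from -0.426 to -0.0478 (direction reversed without VCAM1-high replicate 1). Between VCAM1-negative and VCAM1-low, immediate early genes ran from -0.299 to 0.0303 (without VCAM1-negative replicate 3, and equally without the number-3 libraries) and heat shock from -1.03 to 0.257 (without VCAM1-low replicate 1). Of the other values for named genes and lists 3788 kept direction and call, 687 lost a call and 111 gained one. Depth limits genes near 0.05 RPKM, 1 read per kb at the lowest depth.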

Other observations

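Chaperone genes follow replicate number in the geriatric libraries. The heat shock list (11 genes) averages 9.22, 9.81 and 9.86 log2 units in the number-1 libraries of VCAM1-high, VCAM1-low and VCAM1-negative, 8.34, 8.26 and 8.22 in the number-2 libraries, and 7.60 and 7.61 in the number-3 libraries of VCAM1-high and VCAM1-negative. Middle-aged libraries read 7.83, 8.17 and 8.05. No test was made of this order, and it was picked after the values were seen.

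Transcripts of dividing cells differ between single libraries. Middle-aged replicate 1 has the highest mitosis level (13 genes, 2.60 log2 units, against 0.45 and 1.34 in the other 2), a DNA replication level of 4.88 against 3.55 and 3.63, and 390 RPKM of the differentiation factor Myog. VCAM1-high replicate 3 follows with a mitosis level of 2.32, against 0.45 and 0.83 in its group.

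Of the tests that follow, those on endothelial RNA, depth and a shared batch in the number-3 libraries were chosen only after these were seen to stand apart, and those on adipocytes, on GC content or length and on other splits were fixed earlier. The number-3 libraries of 3 groups stand apart. In the middle-aged and VCAM1-high groups the endothelial list is higher in replicate 3 than in the other 2 (by medians of 3.41 and 1.59 log2 units, 11 of 11 genes in both, the lower value 1.59), which is consistent with endothelial RNA there, though the sort removed CD31+ cells. Transcripts of other cell types rose with it, so the list does not single out endothelial cells. Mean levels in middle-aged replicate 3 are 4.37 log2 units for tenocytes (1.43 and 1.37 in the other 2), 6.26 for fibro-adipogenic progenitors (3.96 and 4.26) and 2.87 for macrophages (1.45 and 0.939). In VCAM1-high replicate 3 they are 5.02 for macrophages (0.934 and 1.66), 3.47 for leukocytes (0.0709 and 0.664) and 5.11 for adipocytes (2.37 and 2.90). The fibro-adipogenic progenitor list is higher in that library too than in the other 2 of its group (3.84 and 3.87). In VCAM1-negative replicate 3 the endothelial list is lower, by -1.22 (11 of 11 genes), so endothelial RNA does not account for that library. Depth stays open: replicate 3 is the deepest library of the middle-aged and VCAM1-high groups, and in 1 group, VCAM1-negative, it lies between the others. Bias by GC content or transcript length (the larger correlation of the 2 is 0.255 in middle-aged, 0.30 in VCAM1-high and 0.174 in VCAM1-negative) and a shared batch or day stay open too. The number-3 libraries correlate at 0.554 between middle-aged and VCAM1-high, 0.403 between the geriatric gates and 0.0808 between middle-aged and VCAM1-negative (lowest of all numbers -0.0246, number 1 of that pair). Middle-aged and geriatric libraries cannot share an animal.

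Adipocyte transcripts in geriatric libraries may be RNA of adipocytes carried past the YFP gate, a hypothesis tested by whether Cfd follows Adipoq. Over the 8 geriatric libraries their Spearman correlation is 0.976 (exact permutation p = 0.000397 over 40320 orders), and Pearson's on the log2 scale is 0.980 (permutation p = 4.96e-05), or 0.909 without the 2 farthest libraries. This is consistent with a common source, since Adipoq is made by adipocytes, with Adipoq at 14.6 and Cfd at 293 RPKM in VCAM1-high replicate 3. The correlation does not show that all of the Cfd comes from there. The permutations treat the 8 libraries as independent, although same-numbered geriatric libraries deviate together, so their p-values may be too small.

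Results were also compared with other splits of the libraries, all of them for 2 groups and 100 drawn at random, the real one included, for the F test. Of 10 splits of 6 libraries, too few for a share under 0.05, as many changed genes came from 10 between VCAM1-negative and VCAM1-high (0, highest other 0), 1 between VCAM1-high and middle-aged (62, highest other 9) and 1 between VCAM1-negative and middle-aged (888, highest other 2). As many lists came from 7 (10, highest other 16), 6 (11, highest other 15) and 4 (13, highest other 19). The number of lists called at the preset correlation thus does not set the real groups apart from other splits. Swapping the gates within replicate numbers gave as many genes in 1 of 4 splits (137, highest other 81). In the F test 3 of 100 splits passed as many genes as the 384 found. The highest, 2005, kept the 3 middle-aged libraries together and the number-2 geriatric libraries together, so it mixes age with replicate number.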
